A study of Homo sapiens with 8 samples.

How the data were processed

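Gene expression was measured on 8 arrays from 2 established human liver cancer cell lines, SK-Hep1 and Huh7, with and without stable knockdown of SMARCB1, a core subunit of the SWI/SNF chromatin remodelling complexes. Samples were placed in 4 groups of 2 arrays by the genotype and cell line recorded for each sample. The groups were SK-Hep1 control (numbered 1 and 2 in the sample titles), SK-Hep1 knockdown (11 and 12), Huh7 control (1 and 2) and Huh7 knockdown (3 and 4). Per the labels' protocols, cells carrying short hairpin RNA were selected with puromycin at 1.25 µg/mL, total RNA was extracted with TRIzol, and biotin-labelled cRNA was made from 0.55 µg of total RNA for an Illumina BeadChip. The titles of the Huh7 controls name GFP and those of the SK-Hep1 controls do not, so the control construct may differ between the lines. The number 11 also stands in the titles of both Huh7 knockdown arrays, and no source used here says whether 11 and 12 mark different hairpins. The sample descriptions give both arrays of a group the same replicate number, and nothing says that they came from separate cultures, so every p-value measures only the spread between these arrays, which may be technical.

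The values analysed were the log2 intensities that the authors deposited in their processed table, with 47319 probes. GenomeStudio version 2011.1 was used upstream, per the submitters' processing notes. The normalization, the background treatment and any further adjustment are not given in the sources used here. The medians of the 8 arrays lay between 6.931 and 6.934 and the quartiles between 6.677 and 8.272, so the arrays had been brought to nearly one distribution. The lowest values were between 5.904 and 5.974 on the log2 scale, and the source of this floor is not given. If background is part of the values, fold changes of dim genes are understated. A table of signals before normalization was not used. Its 16 value columns, for 8 samples, carry only running numbers that match no label, and columns were not assigned by order or by values. Background correction and detection p-values could therefore not be applied as planned, and the log2 values were used as deposited without further normalization.

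The deposited log2 values hold almost no difference between the cell lines. The SD over genes of the difference between the mean of the 4 SK-Hep1 arrays and that of the 4 Huh7 arrays was 0.0291, below the 0.0671 that the spread between replicate arrays alone would give. Among the 35 ways to split the 8 arrays 4 against 4, no other gave less than 0.0647, and 0 of 12384 genes differed by more than 0.5 between the lines. Correlations between arrays of different lines were 0.991 to 0.994, and those between conditions within a line 0.983 to 0.991. A direct comparison of the lines and any statement on the level of a gene in a line were therefore left out. A shift of a gene's mean in a line leaves the difference between knockdown and control in that line as it was. Whether the scale of a gene was also changed within a line is not known, and this would change the sizes of the differences.

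Probes were named through the platform annotation supplied with the table. There were 30110 probes with 1 gene symbol, 8 with several and 17201 with none. Of the named probes, 30071 matched a gene identifier in the RefSeq gene table and 0 symbols needed updating. Background was set from 610 probes for olfactory, taste and vomeronasal receptors, keratin-associated proteins and beta-defensins. Probes were kept when their mean over the 8 arrays was above the 95th percentile of these probes, which was 7.006, and this left 21360 probes (45.14%). The probe with the highest mean stood for its gene, giving 12384 genes of the 20044 named on the array. This filter was chosen after the table had been seen, in place of a planned filter on detection p-values, and the same holds for a stricter one at the 99th percentile.

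Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on 4 group means, with 4 residual degrees of freedom and 1 estimate of the spread per gene for all groups. The contrasts were knockdown minus control in SK-Hep1, the same in Huh7, and the SK-Hep1 difference minus the Huh7 difference. Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over the 12384 genes, with a threshold of 0.05. Shared calls were compared with the product of the 2 call rates and with one-sided Fisher's exact tests across genes. The 24 gene lists, written before the data were examined, were tested with camera at a preset correlation between genes of 0.01, again with the correlation estimated from the residuals, and with fry. Those p-values were adjusted over the 24 lists. With an estimated correlation camera uses the 4 residual degrees of freedom. With the preset correlation it uses far more, set by the number of genes. A call lost with an estimated correlation can therefore come from the few arrays as well as from correlated members. Knockdown and control arrays of a line share no numbers, so no paired fit was made. The precision of every value is limited by the number of arrays, 2 per group.

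The genes named in the text follow a rule set before the data were examined. It takes, per line, the 12 largest rises and the 12 largest falls among genes past the threshold whose knockdown arrays both lay on one side of both control arrays. It adds the 8 genes past the threshold in both lines with the same sign and the 8 with opposite signs, ranked by the smaller of their changes, and up to 4 members per list with the smallest p. SMARCB1 and NUP210, a nucleoporin the study is known to have followed, are always included. The part of the rule that needs detection p-values could not be applied, and 1 gene that the rule names is not reported here. The lists were SWI/SNF subunits, Polycomb subunits, nucleoporins, DNA replication, mitosis, p53 targets, interferon response, inflammatory cytokines and NF-kB targets, hepatocyte, endothelial and immune cell markers, epithelial genes, mesenchymal genes, collagens and matrix, integrins and adhesion, cholesterol synthesis and uptake, fatty acid synthesis and storage, hypoxia and glycolysis, the unfolded protein response with ATF4 targets, YAP targets, Wnt targets, ribosome biogenesis, oxidative phosphorylation, and immediate early genes with stress genes. SMARCB1 was left out of its own list. AXL and NT5E stood in both the mesenchymal and the YAP list.

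Alternatives covered the scaling of the arrays, normalization and fitting within each line, no filter and a stricter filter, the mean of a gene's probes and single probes, a fit of each line alone, a trend with robust spread, a minimum fold of 2, a test against a log2 change of 0.5, array weights, and leaving out each array in turn. The code was tested on simulated data made from the SK-Hep1 comparison over 12384 genes with 200 changed genes. In 5 simulations it recovered 70.8% of the genes changed by 0.5 and 98% of those changed by 1 on the log2 scale, with 4.32% false calls. A list shifted by 0.3 was called in 5 of 5 simulations with either correlation setting. Genes were drawn independently with 1 spread for both lines, and in the list runs no other gene was changed. In the real data the estimated correlation within a list reached 0.457. The simulations therefore check the code and give neither error rates nor power for the real data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.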

Results

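Genome-wide expression was compared between SMARCB1 knockdown and control cells in 2 liver cancer lines. SK-Hep1 is an established line from an adenocarcinoma of the liver that is known for endothelial features, and Huh7 is a hepatoma line that keeps many hepatocyte traits. Each line contributed 2 control and 2 knockdown arrays, and 12384 genes were bright enough to be tested. The SD over genes of the difference between 2 replicate arrays was 0.135 in SK-Hep1 controls, 0.173 in SK-Hep1 knockdown cells, 0.103 in Huh7 controls and 0.115 in Huh7 knockdown cells, all on the log2 scale. Values below are log2 differences, knockdown minus control, with n = 2 arrays per group, and adjusted p-values are from limma with Benjamini-Hochberg adjustment.

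SMARCB1, the targeted gene, was lower on every knockdown array than on every control array of its line. Its brighter probe, ILMN_1758823, read 10.68 and 10.61 in SK-Hep1 controls against 9.30 and 9.67 after knockdown. In Huh7 it read 10.84 and 10.94 in controls against 9.22 and 9.27 after knockdown. The difference was -1.16 ± 0.107 (SE) in SK-Hep1, which left 44.7% of the control signal (adjusted p = 0.000113), and -1.65 ± 0.107 in Huh7, which left 32% (adjusted p = 3.5e-06). The other probe, ILMN_2403458, left 50% and 36.1%. The fall was larger in Huh7, by 0.48 (adjusted p for the difference between lines = 0.0349) and on the other probe by 0.47 (adjusted p = 0.0495). The difference did not pass the threshold when any 1 array other than SK-Hep1 knockdown replicate 11 was left out (adjusted p = 0.0586 to 0.119), and it was 0.30 without SK-Hep1 knockdown replicate 12 and 0.67 without replicate 11. If background signal is part of these values, the percentages overstate what remained. NUP210, which encodes a membrane nucleoporin, fell in both lines, with a difference of -0.65 ± 0.0778 in SK-Hep1 (adjusted p = 0.000527) and -0.58 ± 0.0778 in Huh7 (adjusted p = 0.000311), with no detectable difference between the lines (adjusted p = 0.696). NUP210 was picked because the study is known to have followed it, so its fall is not independent evidence.

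**Figure D1:**
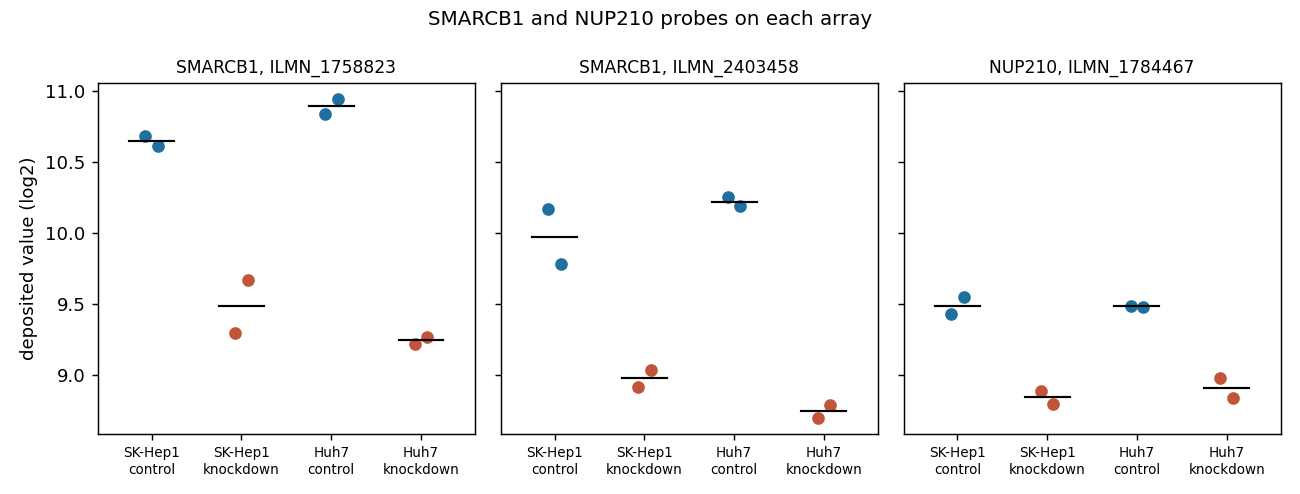
Deposited log2 values (vertical axis) of the 2 SMARCB1 probes and the NUP210 probe on each of the 8 arrays, by group (horizontal axis); points are arrays and bars are means of 2 arrays. In both lines the knockdown arrays of each probe lie below the control arrays, for SMARCB1 probe ILMN_1758823 at 9.22 to 9.67 against 10.61 to 10.94.

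After knockdown in SK-Hep1, the mitosis, cholesterol and fatty acid lists passed the threshold toward lower expression with camera at its preset correlation, and none of these calls held with an estimated correlation (adjusted p = 0.314 for each). The largest single changes were rises. The largest rises were in IL24, a cytokine of the IL-10 family (6.92-fold, 2.79 ± 0.121), GCNT3, which branches mucin-type glycans (4.8-fold, 2.26 ± 0.0861), SERPINA9 (2.26) and the membrane protein gene TM4SF4 (2.20). CSF3, which encodes granulocyte colony-stimulating factor, rose by 1.94, and NPPB, the precursor of B-type natriuretic peptide, by 1.90. Further large rises were in SCG5 (1.85), a chaperone of a prohormone convertase, SPOCD1 (1.79), the heme oxygenase gene HMOX1 (1.63), the kinase gene WNK4 (1.58), the TNF receptor gene TNFRSF1B (1.58) and the neutrophil chemokine gene CXCL6 (1.55). The largest falls were in EFNA1, which encodes ephrin-A1 (3.16-fold, -1.66 ± 0.0782), FILIP1L (-1.55), the glutathione-degrading enzyme gene CHAC1 (-1.46), the desmosome-associated plakin gene PPL (-1.31) and the transcription factor gene KLF4 (-1.30). They were followed by the stress-responsive genes ATF3 (-1.24) and SESN2 (-1.24), SMARCB1 itself (-1.16), the stearoyl-CoA desaturase gene SCD (-1.15), the MHC class II genes HLA-DRA (-1.06) and HLA-DMB (-1.01), and the interferon regulatory factor gene IRF1 (-1.01). Adjusted p-values of these genes ran from 1.15e-06 to 0.00141. Values are from the brightest probe of a gene, and the 2 probes of IL24 ran from 1.62 to 2.79, those of KLF4 from -1.30 to -0.82 and those of ATF3 from -1.24 to -0.65.

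In all, 2089 of 12384 genes passed the threshold in SK-Hep1, 1031 higher and 1058 lower, and 59 of them changed at least 2-fold, 46 higher and 13 lower. Most changes were small, with a median size of 0.356 among the genes past the threshold. The count fell when either SK-Hep1 control array was left out. It was 1087 when the SK-Hep1 arrays were fitted alone, 1212 with normalization within each line and 1200 with array weights. No named gene reversed its direction in any setting tried, but this was largely fixed in advance. Many settings leave the difference itself unchanged, and the largest rises and falls were picked with both knockdown arrays on one side of both controls.

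Of the 24 gene lists, 7 passed the threshold in SK-Hep1, all toward lower expression, and none of these calls held with an estimated correlation between genes. That test has only 4 residual degrees of freedom, so a lost call does not by itself show correlated members. The estimate was 0.36 for mitosis and 0.431 for DNA replication, far above the preset 0.01, so their p-values at the preset correlation may be far too small. For the other lists called it lay between -0.0195 and 0.067. Mitosis genes fell most broadly: 23 of 35 fell and 0 rose (28 fell when adjusted over the list alone), with a median of -0.324 (camera adjusted p = 1.01e-12, adjusted p = 0.314 with an estimated correlation). Examples were the kinesin gene KIF20A (-0.52), the ubiquitin-conjugating enzyme gene UBE2C (-0.45), cyclin B2 (CCNB2, -0.42) and Aurora kinase B (AURKB, -0.48). Of the DNA replication genes 9 of 35 fell and 0 rose (11 fell when adjusted over the list alone, median -0.179, adjusted p = 0.00956, adjusted p = 0.529 with an estimated correlation), among them the polymerase gene POLA1 (-0.30) and the clamp loader gene RFC5 (-0.37). Without control replicate 1 the mitosis list had 10 genes lower and the DNA replication list 0, and without knockdown replicate 12 they had 15 and 1, with 4 DNA replication genes higher and that list's call lost (adjusted p = 0.513). The median of the DNA replication list was -0.271 without knockdown replicate 11 and -0.0689 without knockdown replicate 12, and the 2 probes of UBE2C ran from -0.45 to -0.14. The DNA replication list had 1 gene lower without control replicate 2, 18 without knockdown replicate 11, 4 without either Huh7 control and 5 without either Huh7 knockdown array. POLA1 lost its call without control replicate 1 (adjusted p = 0.0698), control replicate 2 (0.0569) or knockdown replicate 12 (0.0519), and RFC5 without control replicate 1 (0.125) or knockdown replicate 12 (0.0739).

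In the cholesterol list in SK-Hep1 9 of 20 genes fell and 0 rose (12 fell when adjusted over the list alone, median -0.202, adjusted p = 7.69e-06, adjusted p = 0.314 with an estimated correlation). They included mevalonate kinase (MVK, -0.59), the late pathway enzymes DHCR7 (-0.64) and TM7SF2 (-0.56), and lanosterol synthase (LSS, -0.41). In the fatty acid list 7 of 21 fell and 0 rose (7 fell and 1 rose when adjusted over the list alone, median -0.119, adjusted p = 0.0136, adjusted p = 0.314 with an estimated correlation). Besides SCD these included the phosphatidate phosphatase gene LPIN1 (-0.63), fatty acid synthase (FASN, -0.55) and SREBF1 (-0.68), which encodes a master regulator of lipid synthesis. Without control replicate 1 the cholesterol list had 5 genes lower, against 9 with all arrays, and without knockdown replicate 12 its median was -0.355. The 3 probes of LSS ran from -0.41 to -0.25 in SK-Hep1.

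Of the unfolded protein response and ATF4 target genes 13 of 34 fell and 3 rose in SK-Hep1 (13 and 8 when adjusted over the list alone, median -0.0482, adjusted p = 0.0449, adjusted p = 0.369 with an estimated correlation). Those that fell included CHAC1, ATF3, the mTORC1 inhibitor gene DDIT4 (-0.79) and the serine synthesis gene PHGDH (-0.62), which are mostly ATF4 targets. Of the YAP targets 7 of 23 fell and 0 rose (10 and 2 when adjusted over the list alone, median -0.119, adjusted p = 0.0449, adjusted p = 0.314 with an estimated correlation), with GADD45B (-0.98), the tissue factor gene F3 (-0.72) and the kinase gene NUAK2 (-0.63) as examples. Of the nucleoporins 8 of 29 fell and 1 rose (9 and 1 when adjusted over the list alone, median -0.0807, adjusted p = 0.0304, adjusted p = 0.314 with an estimated correlation). NUP210 led the list at -0.65, SEH1L was at -0.34, and NUP50 rose by 0.34. As NUP210 is not independent evidence and the list was not tested without it, part of this call rests on a gene picked beforehand. The ATF4 and YAP lists lost their calls without control replicate 1 (adjusted p = 0.0732 and 0.0621) and without knockdown replicate 11 (0.148 for each), and the nucleoporins without knockdown replicate 12 (0.146). The nucleoporins had 4 genes lower without control replicate 1, 2 without control replicate 2, 5 without either knockdown array, 3 without either Huh7 control and 4 without either Huh7 knockdown array, and the YAP list had 4 lower without control replicate 1 and 3 higher without knockdown replicate 11. The median of the YAP list was -0.196 without control replicate 2, that of the nucleoporins -0.137 without knockdown replicate 11, and the ATF4 list had 0 genes higher without either control. The 2 probes of NUP50 ran from 0.12 to 0.34. NUP50 lost its call without control replicate 1 (adjusted p = 0.0873) and SEH1L without control replicate 2 (0.0877).

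The other lists did not pass the threshold as lists in SK-Hep1, although single members did. Among the inflammatory cytokines and NF-kB targets 8 of 24 rose and 7 fell (9 and 9 when adjusted over the list alone, adjusted p = 0.702). CSF3, CXCL6 and the superoxide dismutase gene SOD2 (0.98) rose, and TNFAIP2 fell (-0.80). Of the collagens and matrix genes 9 of 29 rose and 4 fell (11 and 6 when adjusted over the list alone, adjusted p = 0.123), led by COL6A1 (1.196), COL6A2 (0.98) and COL4A1 (0.95), and 5 rose without control replicate 1. This list had 2 genes lower without either control, and it passed without knockdown replicate 11 (adjusted p = 0.0463). Of the epithelial genes 4 of 17 fell and 0 rose (4 and 0 when adjusted over the list alone, adjusted p = 0.0546), including the keratin genes KRT8 (-0.70) and KRT19 (-0.47) and the adhesion gene EPCAM (-0.68 on its brightest probe, -0.68 to -0.08 over 3 probes), and the list passed without control replicate 2 (adjusted p = 0.0353). Of the Wnt targets 6 of 15 fell and 2 rose (8 and 2 when adjusted over the list alone, adjusted p = 0.0749), with AXIN2 at -0.67 and LEF1 at -0.80. This list had 3 genes lower and 0 higher without control replicate 1, 3 lower without knockdown replicate 12 and 1 higher without control replicate 2. Among the immediate early and stress genes 8 of 29 rose and 9 fell (11 and 10 when adjusted over the list alone, adjusted p = 0.921). HMOX1 and the near-identical heat shock genes HSPA1A (1.46) and HSPA1B (1.51) rose, and the values of this pair are uncertain because their probes can read both genes. The number that rose in this list was 4 without either control array.

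For the remaining lists in SK-Hep1, the numbers that rose and fell, with those adjusted over the list alone in the same order, were as follows. Polycomb subunits had 2 and 6 of 23 (2 and 7, adjusted p = 0.217), with the methyltransferase gene EZH2 at -0.41 and only 2 genes lower without control replicate 1. SWI/SNF subunits other than SMARCB1 had 1 and 1 of 23 (0 and 1, adjusted p = 0.359). The interferon response had 2 and 6 of 28 (3 and 7, adjusted p = 0.299). Without knockdown replicate 11 it had 9 genes lower, a median of -0.169 and a call (adjusted p = 0.0106), and without knockdown replicate 12 it had 5 higher and a median of 0.0732, so its direction turned on 1 array. The p53 targets had 3 and 2 of 24 (3 and 4, adjusted p = 0.943). Hypoxia and glycolysis had 8 and 2 of 33 (8 and 6, adjusted p = 0.293), and mesenchymal genes had 3 and 3 of 20 (3 and 3, adjusted p = 0.52), with SNAI2 at 0.69. Integrins and adhesion had 5 and 1 of 24 (5 and 1, adjusted p = 0.146), with 3 higher without control replicate 1. Ribosome biogenesis had 1 and 2 of 33 (1 and 2, adjusted p = 0.0923) and passed without control replicate 2 (adjusted p = 0.0393), and oxidative phosphorylation 1 and 0 of 32 (0 and 0, adjusted p = 0.956). Of the cell type markers, hepatocyte markers had 4 and 1 of 29 (4 and 1, adjusted p = 0.299), endothelial markers 3 and 0 of 10 (5 and 2, adjusted p = 0.217) and immune cell markers 4 and 2 of 10 (4 and 2, adjusted p = 0.227). Median and mean differed in sign for p53 targets (0.000121 and -0.0494) and for immediate early and stress genes (-0.0354 and 0.0756), and the camera test followed the mean. With 1 SK-Hep1 array left out these medians ran from -0.00343 to 0.0331 and from -0.055 to 0.00972. Counts under 5 in the lists of this paragraph changed by at most 3 genes with 1 array left out. They did so for hypoxia and p53 targets, each with 5 lower without knockdown replicate 11, for mesenchymal genes, with 0 lower without control replicate 1, and for the interferon response.

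After knockdown in Huh7, the hypoxia, NF-kB and DNA replication lists passed the threshold toward higher and the fatty acid and cholesterol lists toward lower expression with camera at its preset correlation. None of these calls held with an estimated correlation (adjusted p = 0.0816, 0.0768, 0.432, 0.21 and 0.214 in that order). The largest rise was in NPPB (10.9-fold, 3.45 ± 0.165), followed by TAGLN, an actin-binding protein of smooth muscle (4.36-fold, 2.12 ± 0.108), and CCL2, a monocyte chemokine (2.12 ± 0.267). LYPD6B (1.97), LRRN3 (1.97), the histone variant gene MACROH2A2 (1.86), the cadherin gene CDH6 (1.85) and TNFRSF19 (1.84) rose by similar amounts. So did BAAT, which conjugates bile acids (1.82), OLR1, a receptor for oxidised LDL (1.804), S100A3 (1.78) and the serine protease gene HABP2 (1.77). The largest fall was in HAMP, which encodes the iron-regulating hormone hepcidin (8.96-fold, -3.16 ± 0.1). THBS4, a thrombospondin, fell as well (-2.39), and ABCG1, a cholesterol exporter, was at -2.09 on its brightest probe, while its 3 probes ran from -2.09 to -0.04. Further falls were in S100P (-1.89), the phospholipase gene PLA2G7 (-1.86), the protease inhibitor gene A2M (-1.83), SPOCK2 (-1.77), SMARCB1 itself (-1.65), ASAP3 (-1.63), DACT3 (-1.63), the cytochrome P450 gene CYP1A1 (-1.56) and the neurotensin gene NTS (-1.55). Adjusted p-values of these genes ran from 1.83e-07 to 0.000219. The 2 probes of TAGLN ran from 0.88 to 2.12.

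In Huh7, 4843 of 12384 genes passed the threshold, 2412 higher and 2431 lower, and 170 of them changed at least 2-fold, 86 higher and 84 lower. The median size of the change among the genes past the threshold was 0.363. Leaving out 1 Huh7 array lowered the count, to 2882 without control replicate 1, 2967 without control replicate 2, 3132 without knockdown replicate 3 and 3033 without knockdown replicate 4.

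Of the 24 lists, 8 passed the threshold in Huh7, 6 toward higher and 2 toward lower expression, and none of these calls held with an estimated correlation between genes. That test has only 4 residual degrees of freedom, so a lost call does not by itself show correlated members. The NF-kB list lost its call although its estimated correlation was -0.021, under the preset 0.01. The epithelial (-0.048) and ribosome biogenesis (-0.00681) lists were under the preset as well. The estimate was 0.0415 for hypoxia, 0.0549 for cholesterol and 0.067 for fatty acid genes. It was far above the preset for DNA replication (0.431) and the interferon response (0.457), so their p-values at the preset correlation may be far too small. Hypoxia and glycolysis genes rose most broadly: 27 of 33 rose and 1 fell (29 and 1 when adjusted over the list alone), with a median of 0.395 (camera adjusted p = 2.26e-10, adjusted p = 0.0816 with an estimated correlation). They included the glucose transporter gene SLC2A1 (1.62), PFKFB3 (1.61) and PFKFB4 (1.51), which set the level of a glycolytic activator, and the hypoxia-induced gene ANKRD37 (1.101). Of the inflammatory cytokines and NF-kB targets 17 of 24 rose and 0 fell (18 and 0 when adjusted over the list alone, median 0.536, adjusted p = 1.44e-07, adjusted p = 0.0768 with an estimated correlation). Besides CCL2 (2.12), these were led by the chemokine genes CXCL8 (1.76) and CXCL2 (0.87) and by NFKB1 (0.79) and TNFAIP3 (1.03), both part of the NF-kB pathway. Of the interferon response genes 14 of 28 rose and 0 fell (15 and 0 when adjusted over the list alone, median 0.255, adjusted p = 0.00296, adjusted p = 0.517 with an estimated correlation), including the RNA sensor gene IFIH1 (0.94), OAS3 (0.99) and HERC6 (0.58). Without knockdown replicate 4 the interferon list had 9 genes higher.

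Of the DNA replication genes 20 of 35 rose in Huh7 and 0 fell (22 and 0 when adjusted over the list alone, median 0.263, adjusted p = 4.44e-06, adjusted p = 0.432 with an estimated correlation). The nucleotide synthesis genes RRM2 (0.76) and TYMS (0.61), the maintenance methylation factor gene UHRF1 (0.85) and POLA1 (0.57) had the smallest p-values, although the 2 probes of POLA1 ran from 0.18 to 0.57 and those of UHRF1 from 0.41 to 0.85. Of the ribosome biogenesis genes 16 of 33 rose and 1 fell (22 and 1 when adjusted over the list alone, median 0.238, adjusted p = 0.00151, adjusted p = 0.0957 with an estimated correlation), with PPAN at 0.43, RRP12 at 0.41 and NOP58 at 0.45. Of the epithelial genes 10 of 17 rose and 1 fell (12 and 1 when adjusted over the list alone, median 0.288, adjusted p = 0.000935, adjusted p = 0.0957 with an estimated correlation), among them EPCAM (1.41), KRT19 (0.69) and the polarity gene CRB3 (0.79). Without control replicate 1 these 3 lists had 10, 9 and 5 genes higher, without control replicate 2 they had 12, 9 and 5, and without knockdown replicate 4 they had 13, 9 and 6. Without knockdown replicate 3 the DNA replication list had 13 and the epithelial list 5.

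In the fatty acid list in Huh7 14 of 21 fell and 2 rose (15 and 2 when adjusted over the list alone, median -0.377, adjusted p = 0.000292, adjusted p = 0.21 with an estimated correlation). GPAM, which starts glycerolipid synthesis (-1.49), FASN (-0.63), SREBF1 (-0.83) and the desaturase gene FADS1 (-0.65) fell, and the lipid droplet coat gene PLIN2 rose (0.69). In the cholesterol list 11 of 20 fell and 1 rose (12 and 1 when adjusted over the list alone, median -0.272, adjusted p = 0.00292, adjusted p = 0.214 with an estimated correlation). These included FDPS (-0.83), IDI1 (-0.61) and LSS (-0.55), and MSMO1 was at -0.81 on its brightest probe while its 3 probes ran from -0.93 to 0.06. The 3 probes of LSS ran from -0.55 to -0.23.

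The other lists did not pass the threshold as lists in Huh7. Of the hepatocyte markers 13 of 29 fell and 4 rose (14 and 4 when adjusted over the list alone, adjusted p = 0.0554), where APOA2 (-0.98), RBP4 (-0.84) and AHSG (-0.71) fell and APOA1 rose (0.99). The number that fell was 8 and 7 without control replicate 1 or 2 and 6 without knockdown replicate 3. The list passed without control replicate 1 or knockdown replicate 4 (adjusted p = 0.0419 for each) and without either SK-Hep1 knockdown array (0.0425). Of the collagens and matrix genes 12 of 29 fell and 2 rose (13 and 3 when adjusted over the list alone, adjusted p = 0.0637), with versican (VCAN) at -1.21 and COL4A1 at 1.22, and 7 fell without any 1 of the 4 Huh7 arrays. This list passed without control replicate 1 (adjusted p = 0.0419). Of the p53 targets 6 of 24 fell and 2 rose (6 and 2 when adjusted over the list alone, adjusted p = 0.332), with the cell cycle inhibitor gene CDKN1A at -0.80. Of the unfolded protein response and ATF4 targets 14 of 34 fell and 6 rose (16 and 9 when adjusted over the list alone, adjusted p = 0.0608), with the stress gene NUPR1 at -1.46. It had 3 genes higher without control replicate 1 or knockdown replicate 4, and it passed without control replicate 1 (adjusted p = 0.0419) and without either SK-Hep1 knockdown array (0.0425). Of the nucleoporins 7 of 29 rose and 3 fell (7 and 3 when adjusted over the list alone, adjusted p = 0.236), with 3 higher without control replicate 1 or knockdown replicate 3. NUP98 had the smallest p in that list, at 0.82 on its brightest probe and 0.16 to 0.82 over 3 probes.

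For the remaining lists in Huh7, the numbers that rose and fell, with those adjusted over the list alone in the same order, were as follows. Mitosis had 15 and 1 of 35 (16 and 2, median 0.136, adjusted p = 0.0918), and the 15 became 7 and 4 without control replicate 1 or 2 and 8 and 6 without knockdown replicate 3 or 4. YAP targets had 9 and 3 of 23 (10 and 4, adjusted p = 0.0608), with NUAK2 at 0.99. The YAP list passed without control replicate 1 (adjusted p = 0.0427) and without either SK-Hep1 knockdown array (0.0425), where 5 fell. Integrins and adhesion had 5 and 4 of 24 (5 and 4, adjusted p = 0.332), with the hyaluronan receptor gene CD44 at 1.43 on its brightest probe and 0.21 to 1.43 over 3 probes. Mesenchymal genes had 5 and 5 of 20 (6 and 5, adjusted p = 0.553), with 2 and 3 without control replicate 1 or knockdown replicate 3 and 3 and 3 without control replicate 2, and Wnt targets had 4 and 4 of 15 (5 and 6, adjusted p = 0.621), with AXIN2 at -0.61. Polycomb subunits had 4 and 8 of 23 (5 and 8, adjusted p = 0.332), with 5 lower without control replicate 1 or knockdown replicate 3 and 4 without knockdown replicate 4, and SWI/SNF subunits other than SMARCB1 had 4 and 2 of 23 (2 and 1, adjusted p = 0.518). Immediate early and stress genes had 13 and 9 of 29 (13 and 9, adjusted p = 0.518), and oxidative phosphorylation had 2 and 2 of 32 (2 and 2, adjusted p = 0.602). Endothelial markers had 2 and 3 of 10 (2 and 3, adjusted p = 0.933), and immune cell markers had 1 and 2 of 10 (1 and 2, adjusted p = 0.307). For the endothelial markers the median was 0.0829 and the mean -0.0637, with the camera test toward lower expression. Counts under 5 in the lists of this paragraph changed by at most 3 genes with 1 array left out, as for SWI/SNF subunits, with 1 higher without control replicate 1.

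**Figure D2:**
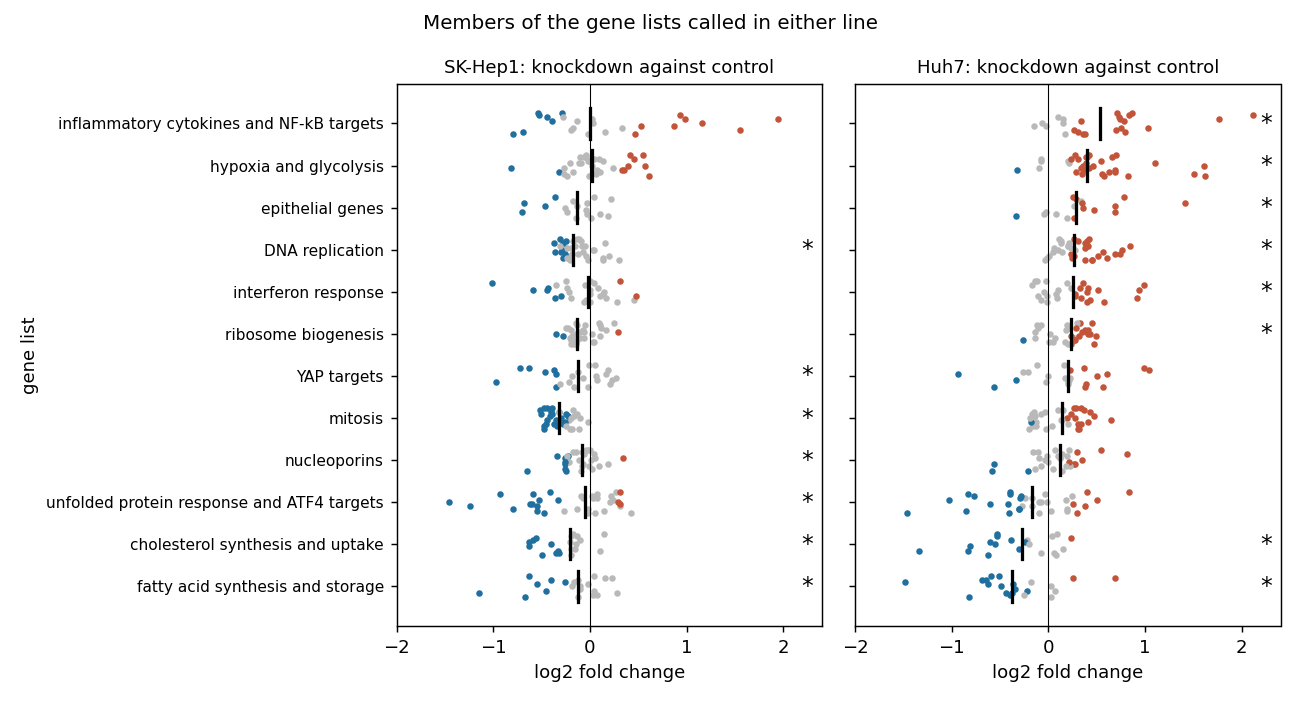
Log2 fold changes (horizontal axis) of the measured members of the 12 gene lists (vertical axis) that passed the threshold in at least 1 line, SK-Hep1 on the left and Huh7 on the right. Points are genes, red where higher and blue where lower past adjusted p 0.05 and grey otherwise, black bars are list medians and asterisks mark lists past the threshold at the preset correlation, of which 0 held with an estimated correlation; hypoxia and glycolysis genes had a median of 0.395 in Huh7 against 0.0193 in SK-Hep1 (-0.0105 to 0.0741 there with 1 array left out), and mitosis genes 0.136 against -0.324.

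Of the 5833 genes past the threshold in either line, 3525 changed differently in the 2 lines by the test of that difference. Genes with a strong shared rise were NPPB (1.90 in SK-Hep1 and 3.45 in Huh7), TM4SF4 (2.20 and 1.34), LYPD6B (1.0 and 1.97), the basement membrane gene COL4A1 (0.95 and 1.22) and CCL2 (0.93 and 2.12). The 2 probes of LYPD6B ran from 0.60 to 1.0 in SK-Hep1. The SK-Hep1 rise of CCL2 was near the threshold (adjusted p = 0.0386), and it did not pass when SK-Hep1 was fitted alone (adjusted p = 0.0615), without SK-Hep1 control replicate 1 (0.186) or 2 (0.111), without either Huh7 control (0.0599) or without either Huh7 knockdown array (0.0545). The SK-Hep1 difference of CCL2 was 0.35 without knockdown replicate 11 and 1.51 without knockdown replicate 12. EFNA1 fell in both lines (-1.66 and -1.11), as did SMARCB1. The strongest opposite changes were a fall in SK-Hep1 with a rise in Huh7 for PPL (-1.31 and 1.28), FILIP1L (-1.55 and 1.19), SOCS2 (-0.80 and 0.99) and DCDC2 (-0.78 and 1.27). SOCS2 was at -0.50 in SK-Hep1 without knockdown replicate 12 and lost its call there without control replicate 1 (adjusted p = 0.0502). The reverse was seen for LFNG, a modifier of Notch receptors (1.17 and -1.34), CD14 (1.04 and -1.07), the angiotensin receptor gene AGTR1 (1.17 and -1.04) and WNK4 (1.58 and -0.90). The 2 probes of CD14 ran from 0.52 to 1.04 in SK-Hep1 and from -1.07 to -0.45 in Huh7.

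Of the genes tested, 1099 passed the threshold in both lines, 567 in the same direction and 532 in opposite directions. Genes higher in both numbered 282 where 201 were expected from the 2 call rates, and genes lower in both 285 where 208 were expected. Genes higher in SK-Hep1 and lower in Huh7 numbered 264 against 202 expected, and the reverse 268 against 206. One-sided Fisher's exact tests across genes, which are not independent replicates, gave p = 9e-11, 9.86e-10, 5.87e-07 and 6.35e-07 in that order (3.6e-10, 1.97e-09, 6.35e-07 and 6.35e-07 after adjustment over the 4 tests). The same-direction count was 299 and 356 without SK-Hep1 control replicate 1 or 2, 329 and 342 without Huh7 control replicate 1 or 2, 357 and 359 without Huh7 knockdown replicate 3 or 4, and 345 with each line fitted alone. The opposite-direction count was 243, 338, 276, 284, 316 and 296 without the same arrays, 831 without SK-Hep1 knockdown replicate 11 and 320 with each line fitted alone. The log2 fold changes of the 2 lines were nearly unrelated across the 12384 genes (Pearson r = 0.0283, Spearman rank correlation 0.001).

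**Figure D3:**
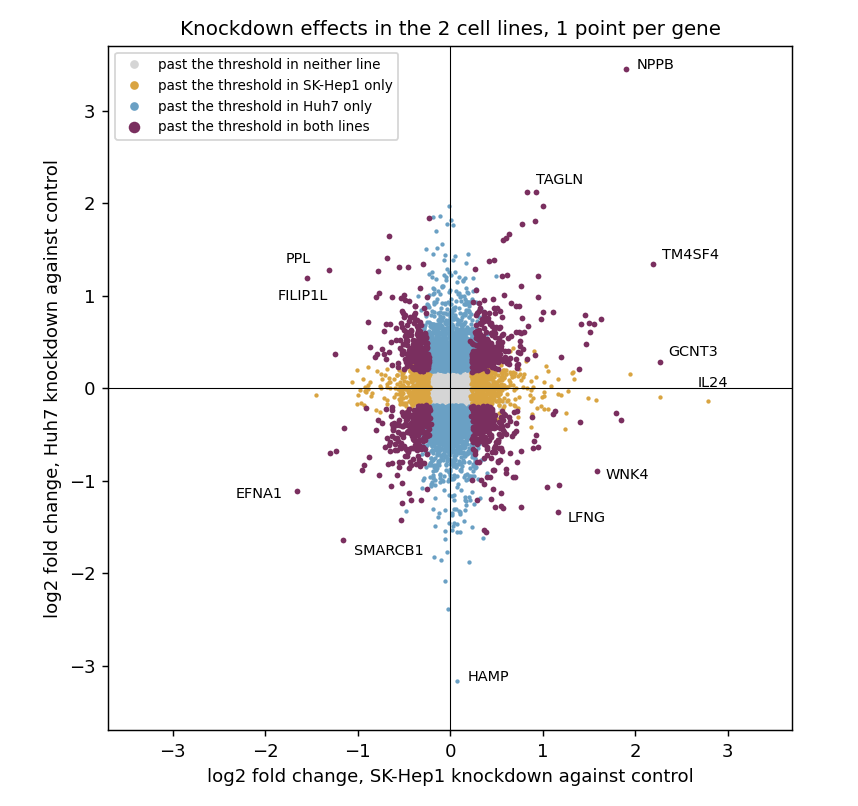
Log2 fold change of each of 12384 genes in SK-Hep1 (horizontal axis) against Huh7 (vertical axis); points are genes, coloured by the line or lines in which they passed adjusted p 0.05, with some of the named genes labelled. The points past the threshold in both lines lie in all 4 quadrants, 567 with the same sign and 532 with opposite signs.

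Tested directly, the change differed between the lines for 3890 genes, with the SK-Hep1 difference above the Huh7 difference for 1892 and below it for 1998. It differed most among the named genes for HAMP (3.23), IL24 (2.94), FILIP1L (-2.74), PPL (-2.59) and LFNG (2.50), given as the SK-Hep1 minus the Huh7 difference. As lists, 11 of 24 differed between the lines, and none did with an estimated correlation. The control construct, the hairpins and the depth of the knockdown may also differ between the lines and cannot be told apart from the line. The deposited values also cannot show whether a gene is expressed in each line, and a gene that is not expressed in a line could not fall there. The change was lower in SK-Hep1 for mitosis (median -0.382, 21 of 35 genes lower and 0 higher, 25 and 0 when adjusted over the list alone, adjusted p = 4.09e-08, adjusted p = 0.34 with an estimated correlation). It was also lower for DNA replication (23 lower and 0 higher of 35, 26 and 0 when adjusted over the list alone, adjusted p = 1.29e-07, adjusted p = 0.369 with an estimated correlation). Hypoxia and glycolysis had 19 lower and 1 higher of 33 (20 and 1 when adjusted over the list alone, adjusted p = 1.5e-06, adjusted p = 0.129 with an estimated correlation). Epithelial genes had 9 and 1 of 17 (11 and 1 when adjusted over the list alone, adjusted p = 0.000312, adjusted p = 0.129 with an estimated correlation). Ribosome biogenesis had 14 and 0 of 33 (14 and 0 when adjusted over the list alone, adjusted p = 0.00034, adjusted p = 0.129 with an estimated correlation). The inflammatory and NF-kB list had 13 and 5 of 24 (15 and 5 when adjusted over the list alone, adjusted p = 0.00384, adjusted p = 0.129 with an estimated correlation).

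The interferon response had 11 lower and 2 higher of 28 (13 and 2 when adjusted over the list alone, adjusted p = 0.00528, adjusted p = 0.613 with an estimated correlation). YAP targets had 11 and 3 of 23 (11 and 3 when adjusted over the list alone, adjusted p = 0.00637, adjusted p = 0.132 with an estimated correlation), and nucleoporins 10 and 2 of 29 (10 and 2 when adjusted over the list alone, adjusted p = 0.00839, adjusted p = 0.306 with an estimated correlation). The change was higher in SK-Hep1 for hepatocyte markers (9 higher and 4 lower of 29, 15 and 5 when adjusted over the list alone, adjusted p = 0.0132, adjusted p = 0.144 with an estimated correlation). It was likewise higher for collagens and matrix (12 and 3 of 29, 14 and 3 when adjusted over the list alone, adjusted p = 0.0105, adjusted p = 0.319 with an estimated correlation). For the hepatocyte markers the median was 0.00521 in SK-Hep1 and -0.154 in Huh7, so their difference came mostly from the lower values in Huh7 knockdown. Among lists not called, median and mean differed in sign for integrins (0.0384 and -0.0185) and for the unfolded protein response and ATF4 targets (0.0551 and -0.0203), with the test following the median. They also differed for oxidative phosphorylation (-0.00565 and 0.0146), where the test followed the mean, and for immediate early genes (-0.00352 and 0.00616), where it followed the median. With 1 array left out, the medians of these lists ran from -0.0251 to 0.0873, from 0.0219 to 0.0961, from -0.00461 to 0.0289 and from -0.0366 to 0.027 in that order. The cholesterol and fatty acid lists, called lower in each line, did not differ detectably between them (adjusted p = 0.972 and 0.271), and with an estimated correlation neither was called in SK-Hep1 (adjusted p = 0.314 and 0.314) or in Huh7 (0.214 and 0.21). Without SK-Hep1 knockdown replicate 12 the interferon and collagen lists lost their calls (adjusted p = 0.052 for each), and 5 collagen and matrix genes were lower there, against 1 without SK-Hep1 control replicate 2 or Huh7 knockdown replicate 4. The DNA replication list had 15 genes lower without SK-Hep1 control replicate 1, 12 without Huh7 control replicate 1 and 15 without Huh7 knockdown replicate 4. Ribosome biogenesis had 9, 8 and 8 without SK-Hep1 control replicate 1, Huh7 control replicate 1 and Huh7 control replicate 2, and the nucleoporins had 6 without Huh7 control replicate 1. The count of genes whose change differed fell to 2562 without Huh7 control replicate 1 and to 2533 without Huh7 control replicate 2.

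The design also implies a comparison of the untreated lines. The deposited values do not allow it, because the mean of each gene hardly differs between the 4 SK-Hep1 and the 4 Huh7 arrays, with 0 of 12384 genes more than 0.5 apart on the log2 scale.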

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

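All tests in this part were set before the results were seen, except those of CD74, HLA-DPA1, MYLIP, APOE, ABCA1, HJV, ACTG2, KNG1 and SERPINC1, genes chosen after their values were seen, and the 2 ratios outside the pattern weighed last. Each result below stands here because the effect of the knockdown differed between the 2 lines by limma's test of that difference, or for lists by camera (adjusted p under 0.05). Values are the SK-Hep1 minus the Huh7 log2 difference, so a value above 0 means a higher change in SK-Hep1. They cannot show whether a gene is expressed in each line.

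The number of such genes was 3890 of 12384. Among the gene lists the median difference was -0.382 for mitosis, -0.47 for DNA replication, -0.404 for hypoxia and glycolysis, -0.406 for epithelial genes, -0.246 for ribosome biogenesis, -0.47 for inflammatory cytokines and NF-kB targets, -0.279 for the interferon response, -0.243 for YAP targets, -0.217 for nucleoporins, 0.236 for collagens and matrix and 0.274 for hepatocyte markers. None of these list calls held with an estimated correlation between genes, where the adjusted p-values ran from 0.129 to 0.613. Without SK-Hep1 knockdown replicate 12 the interferon and collagen lists lost their calls (adjusted p = 0.052 for each), and the median of the YAP targets was -0.383.

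Genes past the threshold in both lines with opposite signs and a difference above 0 were SCG5 (2.2), SPOCD1 (2.05), WNK4 (2.48), LFNG (2.5), CD14 (2.11), AGTR1 (2.22) and CDKN1A (1.11). In the same class, a difference below 0 was seen for FILIP1L (-2.74), PPL (-2.59), ATF3 (-1.62), TNFRSF19 (-2.07), SOCS2 (-1.79), DCDC2 (-2.05), UBE2C (-0.71), TM7SF2 (-0.79), F3 (-1.09) and NUAK2 (-1.62). POLA1 (-0.87) was also of this class, with TNFAIP2 (-1.17), EPCAM (-2.09), KRT8 (-1.39), KRT19 (-1.15), CXCL2 (-1.15), NFKB1 (-1.18), PPAN (-0.78), IFIH1 (-1.38) and EZH2 (-0.74). The SK-Hep1 call of CDKN1A (0.32) was lost with the line fitted alone (adjusted p = 0.0529), with normalization within lines (0.0577) and without SK-Hep1 control replicate 2 (0.0513). That of POLA1 (-0.30) was lost with the line fitted alone (0.0693), with normalization within lines (0.0665), with the mean of its probes (0.0554), and without SK-Hep1 control replicate 1 (0.0698), control replicate 2 (0.0569) or knockdown replicate 12 (0.0519). Without SK-Hep1 control replicate 1, SOCS2 (0.0502) and PPAN (0.0574) lost theirs, and SOCS2 was at -0.50 in SK-Hep1 without knockdown replicate 12. The 2 probes of ATF3 ran from -0.09 to 0.37 in Huh7, so its sign there differs by probe. Those of CD14 ran from 0.52 to 1.04 in SK-Hep1 and from -1.07 to -0.45 in Huh7, those of UBE2C from -0.45 to -0.14 and from 0.27 to 0.54, and those of F3 from 0.22 to 0.36 in Huh7.

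Genes past the threshold in both lines with 1 sign and a difference above 0 were SMARCB1 (0.48), GCNT3 (1.98), TM4SF4 (0.86), HMOX1 (0.88), CXCL6 (0.85), HSPA1A (0.67), HSPA1B (0.91), FDPS (0.5) and VCAN (0.89). In the same class, a difference below 0 was seen for NPPB (-1.55), EFNA1 (-0.55), KLF4 (-0.6), SESN2 (-0.56), SCD (-0.71), TAGLN (-1.3), CCL2 (-1.19), LYPD6B (-0.97), OLR1 (-0.88), S100A3 (-1.0), DHCR7 (-0.39), SLC2A1 (-1.01) and PFKFB3 (-1.04). The difference did not pass for SMARCB1 without any 1 array other than SK-Hep1 knockdown replicate 11 (adjusted p = 0.0586 to 0.119), and it was 0.30 without SK-Hep1 knockdown replicate 12. For CCL2 (0.0784 to 0.112) and OLR1 (0.0895 to 0.132) it did not pass without any 1 control array or Huh7 knockdown array. Without SK-Hep1 knockdown replicate 12 it was -0.61 for CCL2 and -1.33 for OLR1, and without replicate 11 it was -0.43 for OLR1 and -0.37 for SESN2. SESN2 did not pass without SK-Hep1 control replicate 2 (0.0683), Huh7 control replicate 2 (0.072) or Huh7 knockdown replicate 3 (0.0587) or 4 (0.0519). DHCR7 did not pass without SK-Hep1 control replicate 1 (0.0675) or any 1 Huh7 array (0.0594 to 0.0786), nor FDPS without Huh7 control replicate 2 (0.0517) or knockdown replicate 4 (0.0595). The SK-Hep1 call of CCL2 itself was lost with the line fitted alone (0.0615), with a trend and robust spread (0.18) and without any 1 array other than the SK-Hep1 knockdown arrays (0.0545 to 0.186).

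Genes past the threshold in SK-Hep1 and not in Huh7 and a difference above 0 were IL24 (2.94), SERPINA9 (2.36), CSF3 (1.79), TNFRSF1B (1.71), NUP50 (0.43), COL6A1 (1.27), COL6A2 (1.17) and SNAI2 (0.72). In the same class, a difference below 0 was seen for CHAC1 (-1.38), HLA-DRA (-1.12), HLA-DMB (-0.84), IRF1 (-1.2), KIF20A (-0.62), CCNB2 (-0.28), DDIT4 (-0.98), GADD45B (-0.95), RFC5 (-0.5), SEH1L (-0.44) and LEF1 (-0.56). The difference did not pass for CCNB2 without any 1 array other than SK-Hep1 knockdown replicate 11 (adjusted p = 0.0763 to 0.149). Without Huh7 knockdown replicate 4 it did not pass for RFC5 (0.0501) and SEH1L (0.0583). The SK-Hep1 calls of NUP50 and RFC5 were lost with the line fitted alone (0.0549 and 0.0555) and without SK-Hep1 control replicate 1 (0.0873 and 0.125). RFC5 lost its call without SK-Hep1 knockdown replicate 12 (0.0739) as well, and SEH1L without SK-Hep1 control replicate 2 (0.0877).

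Genes past the threshold in Huh7 and not in SK-Hep1 and a difference above 0 were HAMP (3.23), THBS4 (2.36), ABCG1 (2.02), S100P (2.08), PLA2G7 (1.76), A2M (1.65), SPOCK2 (1.74), ASAP3 (1.57) and DACT3 (1.98). CYP1A1 (1.66) was also of this class, with NTS (1.62), GPAM (1.32), IDI1 (0.4), APOA2 (0.97), RBP4 (0.87), AHSG (0.7) and NUPR1 (1.44). In the same class, a difference below 0 was seen for LRRN3 (-1.98), MACROH2A2 (-1.98), CDH6 (-2.04), BAAT (-1.81), HABP2 (-1.81), PFKFB4 (-1.77), ANKRD37 (-1.19), CXCL8 (-1.73), TNFAIP3 (-1.21), RRM2 (-0.72) and UHRF1 (-1.16). TYMS (-0.84) was also of this class, with PLIN2 (-0.46), CRB3 (-0.74), RRP12 (-0.48), NOP58 (-0.6), OAS3 (-1.34), HERC6 (-0.58), APOA1 (-0.88), NUP98 (-0.87) and CD44 (-1.38). The difference did not pass for IDI1 without Huh7 control replicate 1 (adjusted p = 0.0568) or knockdown replicate 3 (0.0561).

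Among the genes chosen after their values were seen, the differences were CD74 (-0.92), HLA-DPA1 (-0.78), MYLIP (1.32), APOE (1.12), ABCA1 (1.24), HJV (1.5), ACTG2 (-1.26), KNG1 (1.52) and SERPINC1 (1.48). That of CD74 did not pass without SK-Hep1 control replicate 1 (adjusted p = 0.0532) or 2 (0.0501) or Huh7 control replicate 1 (0.0546), and it was -0.57 without SK-Hep1 knockdown replicate 12.

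Mitosis genes were lower after knockdown in SK-Hep1 and DNA replication genes higher in Huh7, by mean differences of -0.312 and 0.317 over the lists, but neither list call held with an estimated correlation between genes (adjusted p = 0.314 and 0.432). A single array does not account for this, since the fewest mitosis genes called lower in SK-Hep1 with 1 array left out was 10 (without SK-Hep1 control replicate 1) and the fewest DNA replication genes called higher in Huh7 was 10 (without Huh7 control replicate 1). The difference between conditions was 2.27 times the larger replicate difference for mitosis in SK-Hep1 and 20.1 times for DNA replication in Huh7 (outside the pattern, 5.94 for mitosis in Huh7 and 0.616 for DNA replication in SK-Hep1), but the bound of 2 set beforehand excludes no spread between cultures, since both arrays of a group may be technical repeats. That spread and the culture state of the wells cannot be told apart from the knockdown, since culture day, passage and density are not given and 0 culture labels differ between groups. An effect of the knockdown on proliferation that differs by line stays open as a hypothesis.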

How the results depend on the processing

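The main filter on dim probes, the stricter one and the array weights were chosen after the data had been seen. The other settings were chosen before, although most of them use that main filter. Over 164 results for named genes and all settings there were 3112 values, of which 2911 kept their direction and side of the threshold, 201 lost the threshold, 0 gained it and 0 reversed. The absence of reversals was largely fixed in advance. Many settings leave the difference itself unchanged, and the largest changes were picked with both knockdown arrays on one side of both controls. A minimum fold of 2 ended 85 gene calls and the test against a log2 change of 0.5 ended 77, because both ask for larger changes. The other settings ended 39 calls in 12 gene results, all in SK-Hep1. Of these calls, 7 were lost with each line fitted alone, where only the estimate of the spread changes. The cause of the others was not tested.

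The number of genes changed in SK-Hep1 was 2089, against 1087 with each line fitted alone, 1212 with normalization and fit within each line, 1200 with array weights, 59 with a minimum fold of 2 and 69 when tested against a log2 change of 0.5. Of the 1212 genes, 1199 were among the 2089, all with the same sign. In Huh7 the count was 4843, against 6078 with each line fitted alone, 6106 with normalization and fit within each line and 6359 with array weights. It was 170 with a minimum fold of 2 and 290 when tested against a log2 change of 0.5. Genes changed in both lines in the same direction numbered 567, against 345 with each line fitted alone, 5 with a minimum fold of 2 and 7 against a log2 change of 0.5. In opposite directions they numbered 532, against 320, 5 and 4. Genes whose change differed between the lines numbered 3890, against 316 and 323 with the last 2 settings. A fit of each line alone leaves the differences as they are and changes only the spread estimate and its degrees of freedom. Replicate arrays differed more in SK-Hep1 (SD 0.135 and 0.173) than in Huh7 (0.103 and 0.115). Calls lost in SK-Hep1 with that fit therefore rested on sharing 1 spread with Huh7. The cause of the lower SK-Hep1 count with normalization within lines was not tested further.

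Gene lists past the threshold numbered 7 in SK-Hep1, against 0 with an estimated correlation, 16 with fry and 11 with single probes. In Huh7 they numbered 8, against 0, 18 and 13, and 13 without a filter on dim probes. Between the lines they numbered 11, against 0 with an estimated correlation. Fry does not compare a list with other genes, so its counts answer another question. The test with an estimated correlation rests on 4 residual degrees of freedom, so its counts of 0 do not single out correlated members as the reason.

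With 1 array left out in turn, the lone array of its group was assumed to vary like the other groups. Counts ran from 928 to 2446 genes in SK-Hep1, 2882 to 5607 in Huh7 and 2533 to 4500 for the difference between lines, and from 299 to 677 shared genes with the same and 243 to 831 with opposite directions. Lists past the threshold ran from 5 to 9 in SK-Hep1, 8 to 12 in Huh7 and 9 to 11 between the lines. The SMARCB1 difference ran from -1.349 to -0.976 in SK-Hep1 and from -1.697 to -1.593 in Huh7.

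No paired analysis was possible because the knockdown and control arrays of a line share no replicate numbers. Background correction, detection p-value filters, a slide block and the comparison of the untreated lines, with its replicate block, were not run. Signal over background limits small changes of dim genes, which are understated if the deposited values include background.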

Other observations

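The gene lists of this part and the genes CD74, CIITA, HLA-DPA1, MYLIP, APOE, ABCA1, HJV, MT1F, MT1G, ACTG2, KNG1 and SERPINC1 were chosen after the results had been seen, as were the tests on the line means. The fit of each line alone was planned; the expectation within strata of level and spread and the test of scaling were added after the data had been seen, with their bounds set before their own results. Adjusted p-values of these 9 lists are over the 9 alone. Over all 33 lists each call given here also passed, except 3 named below, but the wider adjustment does not undo the choice. Several lists hold genes already named above for their large changes, among them HLA-DRA, HLA-DMB, HAMP, ABCG1, TAGLN and S100P. Their p-values test a pattern on the data that led to it and are not independent support. MHC class II genes fell in SK-Hep1, 10 of 12 (11 when adjusted over the list alone, median -0.626, adjusted p = 1.35e-07, adjusted p = 0.275 with an estimated correlation). The estimated correlation was 0.757 against the preset 0.01, so the p-value at the preset correlation may be far too small. CD74 was at -1.0, HLA-DPA1 at -0.76 and their regulator CIITA at -0.52. Without SK-Hep1 knockdown replicate 12 these were -0.65, -0.51 and -0.25, and CIITA lost its call (adjusted p = 0.104), as it did without control replicate 1 (0.179) or 2 (0.0794) and with the line fitted alone (0.0595). In Huh7 0 rose and 0 fell (adjusted p = 0.996), and these values cannot show whether the genes are expressed there. Metallothioneins, which bind zinc and copper, rose in both lines, 5 of 7 in SK-Hep1 (median 0.407, adjusted p = 0.000814, adjusted p = 0.135 with an estimated correlation) and 5 in Huh7 (median 0.421, adjusted p = 0.00699, adjusted p = 0.0754 with an estimated correlation). The genes that rose were only partly the same. MT1E, MT1F (0.56 and 0.57) and MT1G (0.66 and 0.56) rose in both lines. MT1X (0.382) and MT2A (0.407) passed only in SK-Hep1, and MT1H (0.421) and MT1M (0.846) only in Huh7. The list did not differ detectably between the lines (camera adjusted p = 0.914). Members of this family are near-identical, so their single values are uncertain.

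In Huh7, LXR targets fell, 8 of 10 (median -0.717, adjusted p = 5.13e-06, adjusted p = 0.0754 with an estimated correlation), with MYLIP at -0.78 and APOE at -0.65. In SK-Hep1 3 rose and 3 fell (adjusted p = 0.747; 1 rose without control replicate 2), with the cholesterol exporter gene ABCA1 at 1.01, MYLIP at 0.54 and APOE at 0.47. The SK-Hep1 calls of MYLIP and APOE were lost without control replicate 2 (adjusted p = 0.082 and 0.107), MYLIP was at 0.33 without knockdown replicate 12, and APOE was at 0.30 and lost its call without knockdown replicate 11 (0.0556). Of the iron handling genes 6 of 13 fell in Huh7 and 2 rose (median -0.185, adjusted p = 0.00951, adjusted p = 0.0754 with an estimated correlation), with HAMP at -3.16 and its upstream co-receptor gene HJV at -1.21. Of the complement and coagulation genes 13 of 26 fell there and 5 rose (median -0.337, adjusted p = 0.008, adjusted p = 0.0754 with an estimated correlation), with KNG1 at -1.49 and SERPINC1 at -1.32, and without Huh7 control replicate 2 the median was -0.179 and 3 rose. Calponins, smooth muscle and actin genes rose in Huh7, 9 of 15 with 1 lower (median 0.293, adjusted p = 0.000159, adjusted p = 0.0754 with an estimated correlation), with ACTG2 at 1.45. MHC class I genes rose in Huh7, 9 of 14 with 2 lower (adjusted p = 0.0096, adjusted p = 0.221 with an estimated correlation). In SK-Hep1 2 of 15 smooth muscle and actin genes rose and 1 fell (median 0.175, adjusted p = 0.00604, adjusted p = 0.135 with an estimated correlation), with 4 higher without knockdown replicate 12 and 1 without control replicate 1, knockdown replicate 11 or any 1 Huh7 array. The SK-Hep1 tests of iron handling, MHC class I and S100 genes passed over the 9 lists (adjusted p = 0.0461, 0.047 and 0.047) and did not pass over all 33 (0.0564, 0.0682 and 0.0689) or with an estimated correlation (0.211, 0.288 and 0.288). S100 genes in Huh7 (adjusted p = 0.122), complement genes in SK-Hep1 (adjusted p = 0.159) and drug and steroid metabolism in SK-Hep1 (0.289) and Huh7 (0.0875) did not pass, although the last did without Huh7 control replicate 1 (0.042).

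The deposited table holds almost no difference between the cell lines, although SK-Hep1 and Huh7 are different lines. The SD over genes of the difference of line means was 0.0291, under the 0.0671 expected from the spread between replicates and under every other split of the arrays (0.0647 to 0.205). Removal of each gene's line mean before deposit predicts such a value and is a likely explanation, as a hypothesis found on the same data. Arrays from 1 cell line would not by themselves give a value under the spread between replicates, but after such a removal the value would be as low for 1 line as for 2, so 0.0291 does not decide whether the arrays came from 1 line.

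Calls were shared between the lines more often than chance in all 4 combinations of directions, with a mean ratio of 1.35 (1.3 to 1.39 over 200 resamples of genes) and of 7.76 when tested against a log2 change of 0.5, there on only 2 to 4 shared genes per combination. A spread pooled over both lines is not the whole cause, since the mean ratio was 1.25 (1.19 to 1.3) with each line fitted alone, where it was 1.12 for genes higher in SK-Hep1 and lower in Huh7. With the expectation summed within 100 strata of the level and spread of genes, the ratio was 1.23 (1.19 to 1.28). This does not exclude level and spread as a cause, since a spread estimated on 4 residual degrees of freedom leaves differences within a stratum. The pooled spread and the strata were not removed together, and the intervals treat genes as independent. A scaling of each gene within each line by the authors may contribute and cannot be told apart, because the log ratio of the variances in the lines had an SD of 1.56, between 1.37 for independent variances and 1.85 for random pairs of genes of like level, and real effects widen this SD, so that its planned bound was too weak. That some genes respond to many perturbations whatever their direction stays open and was not tested.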
